A study of Saccharomyces cerevisiae and Saccharomyces x bayanus
Saccharomyces cerevisiae with 5 samples.

How the data were processed

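Single-cell transcript counts of wild-type Saccharomyces cerevisiae were analysed in 4 treatment libraries, labelled DMSO, guanine, MPA, and guanine and MPA, with 1 library per treatment. MPA is mycophenolic acid, an inhibitor of IMP dehydrogenase, the enzyme that commits IMP to GMP synthesis. Per the labels' protocols, cells were grown for 18 h in CSM medium with glucose, treated at 10 uM, and profiled with Drop-seq, a droplet method that tags the transcripts of one cell with the barcode of one bead. A library of mixed S. cerevisiae and S. bayanus cells, not treated with any compound, completed the series of 5 libraries.

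The deposited values were whole-number counts of transcripts per gene and barcode, taken here as counts of unique molecular identifiers (UMIs), and no scaling had been applied to them. The submitters' processing notes name the genome build R64 and the tool Seurat, without a version. The aligner, the counting tool, the collapsing of UMIs and the choice of barcodes were not given in the sources used here. Of 6966 gene names found in the 4 tables, 6012 matched the R64 annotation by locus tag or symbol, and the names without a match held 2.23% of UMIs. Chromosome positions are those of this annotation. The tables held 0 genes of the mitochondrial genome, so transcripts from that genome were not analysed here.

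UMI counts were summed over the barcodes of a library and divided by the library's total to give CPM, the counts scaled to a common library total. The ratio of CPM between a pair of libraries was given an exact conditional 95% interval (Clopper-Pearson on the 2 counts). Single values have exact Poisson intervals, and shares of barcodes have Clopper-Pearson intervals. All of these intervals cover counting error only. With 1 library per treatment there was no replicate check of any difference, so no p-value, standard error or count of changed genes was computed, and the ratios compare these libraries rather than the treatments. Genes were compared where the pair of libraries held at least 50 UMIs.

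Gene lists were summarised by the median log2 ratio of their members with at least 50 UMIs. That median was placed among 10000 random lists of the same size matched on mean expression in 20 strata, as a percentile that describes these libraries. A count of 0.5 was added before log2 ratios of lists and correlations. The 34 lists, the comparisons, the rule for named genes over all barcodes and most alternatives were fixed before the data were examined. The text reports the GMP synthesis and purine synthesis lists in every comparison, and otherwise the lists whose median lay in the outer 5% at either end in ribosomal-protein-rich barcodes and in the outer 10% on the same side in low-cytosine barcodes, where that list could be measured. This filter was chosen after the data were seen, and the other lists are left out.

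The planned comparisons summed all deposited barcodes. Barcodes were then found to fall into a group with many ribosomal protein transcripts and a group with almost none, and a division at 5% of UMIs from cytosolic ribosomal protein genes was added after the data were seen. Barcodes at or above this share are called rich and the others poor. Because this division uses the outcome of one of the lists, a separate choice that uses no gene was added: barcodes with at most 2 cytosines among their 12 bases, called low-cytosine barcodes. A further choice took barcodes with at least 3% of UMIs from glycolysis and translation factor genes. Cells were not clustered, no cell types were assigned, and no doublet caller was run, so barcodes that hold more than 1 cell remain in all sums.

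Genes were named by a rule. Among genes with at least 50 UMIs in the pair of libraries, the 12 highest and 12 lowest by the interval bound nearest to 1 were named (5 and 5 for guanine and MPA against DMSO and against guanine). Up to 4 members per list with the largest such bound were added, and always the IMP dehydrogenase genes, GUA1 and the purine synthesis genes. Of these added genes the text prints only a part in each comparison. The rule was applied in rich barcodes. There the bound was taken after removing, for each gene, the barcode that held most of its UMIs. That step was added after the data were seen, and the printed ratios keep that barcode unless stated. Over all barcodes, where most UMIs of the leading genes often came from a single barcode, only the first 2 in each direction are named. Members of near-identical gene pairs and overlapping genes are reported as uncertain, since how shared reads were counted is not given in the sources used here.

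Relations between comparisons were described by Pearson and Spearman correlations of log2 ratios across genes. Genes are not independent replicates, so no p-value is attached. Comparisons that share the DMSO library were set beside 20 Poisson simulations without any effect. To compare depth-dependent values, each barcode was thinned to 500 UMIs and shallower barcodes were left out.

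The interval and list procedures were tested on simulated Poisson counts drawn from the real totals over all barcodes, with 200 genes changed by known folds in each comparison. The draws held no clumping of UMIs in single barcodes, so the shares below describe counting error alone. Rich barcodes were not simulated. For MPA against DMSO (5703 genes) intervals held the true ratio for 95.6% of genes, and intervals excluded 1 for 96.0% of the genes changed 2-fold. For guanine against DMSO (4785 genes) the 2 shares were 95.8% and 84.0%. For guanine and MPA they were 96.0% and 93.0% against DMSO (5511 genes), 96.0% and 94.0% against MPA (5795 genes), and 95.7% and 89.0% against guanine (5237 genes).

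Alternatives were scaling by median of ratios, totals without ribosomal protein genes, minimums of 10 and 200 UMIs, barcodes at or above the median depth, removal of the 5% of barcodes with most UMIs, the mean of barcode CPM, thinning, unmatched random lists, the barcode choices above, and, for each gene, removal of the barcode that held most of its UMIs. The mixed-species table listed no gene of S. bayanus, so the planned assignment of barcodes to species was left out. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.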

Results

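Drop-seq transcript counts were collected from wild-type yeast grown for 18 h and treated with DMSO, the control, or with 10 uM guanine, MPA, or guanine and MPA together. The series asks how MPA, which blocks the synthesis of guanine nucleotides from IMP, and guanine, which cells can salvage into the same nucleotides, alter mRNA levels. Each treatment had 1 library. The DMSO library held 527 barcodes and 866463 UMIs, the guanine library 384 barcodes and 450328 UMIs, the guanine and MPA library 794 barcodes and 1113447 UMIs, and the MPA library 857 barcodes and 1359160 UMIs. Median UMIs per barcode were 1174 with DMSO (95% interval over barcodes 1084 to 1264), 902.5 with guanine (850 to 971), 913 with guanine and MPA (862 to 965) and 962 with MPA (902 to 1020). The median number of genes per barcode was 605, 530.5, 517.5 and 514 in the same order. Thinned to 500 UMIs per barcode, the medians were 331, 342, 341 and 307 genes, after 32, 73, 119 and 103 shallower barcodes were left out.

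Transcripts of cytosolic ribosomal proteins separated the barcodes of every library into 2 groups. Rich barcodes had a median of 31.3% of UMIs from these genes with DMSO, 33.1% with guanine, 18.3% with guanine and MPA and 26.4% with MPA, whereas poor barcodes had medians of 0.756%, 0.727%, 0.576% and 0.402%. Poor barcodes made up 45.4% of barcodes with DMSO (Clopper-Pearson interval 41.0 to 49.7), 13.5% with guanine (10.3 to 17.4), 51.1% with guanine and MPA (47.6 to 54.7) and 76.8% with MPA (73.8 to 79.6). The division at 5% is a point on a range rather than a cell type. Between 3% and 7% lay 3 barcodes with DMSO, 0 with guanine, 21 with guanine and MPA and 14 with MPA. MRS2, which encodes a mitochondrial magnesium channel, took 11.6% of UMIs in poor barcodes with DMSO, 12.96% with guanine, 8.41% with guanine and MPA and 7.39% with MPA, against 0.972%, 0.950%, 1.10% and 1.78% in rich barcodes. Cytosine made up 48.7%, 41.3%, 45.8% and 45.1% of the bases of poor barcodes in that order of libraries, and 25.7%, 25.9%, 27.6% and 28.7% of the bases of rich barcodes. The comparisons below were therefore made in rich barcodes, with 288, 332, 388 and 199 barcodes and 529119, 397782, 548501 and 277013 UMIs, and the planned sums over all barcodes are given for lists and rule-ranked genes whose direction differed there. The 20 genes highest in poor barcodes held 1.56%, 1.54%, 2.03% and 3.47% of rich-barcode UMIs, so the rich barcodes of the MPA library carried the largest such share of the 4 libraries. Relative to the share of the same genes in poor barcodes, this put the admixture of the poor-barcode profile in rich barcodes at 6.13% with DMSO, 5.53% with guanine, 9.29% with guanine and MPA and 18.7% with MPA. The estimate is rough, since for some genes it gives more CPM than rich barcodes held. It gives 433 CPM of YAR028W with DMSO against 56.7 held, and 1404 CPM of TIM11 with guanine and MPA against 308.

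**Figure D1:**
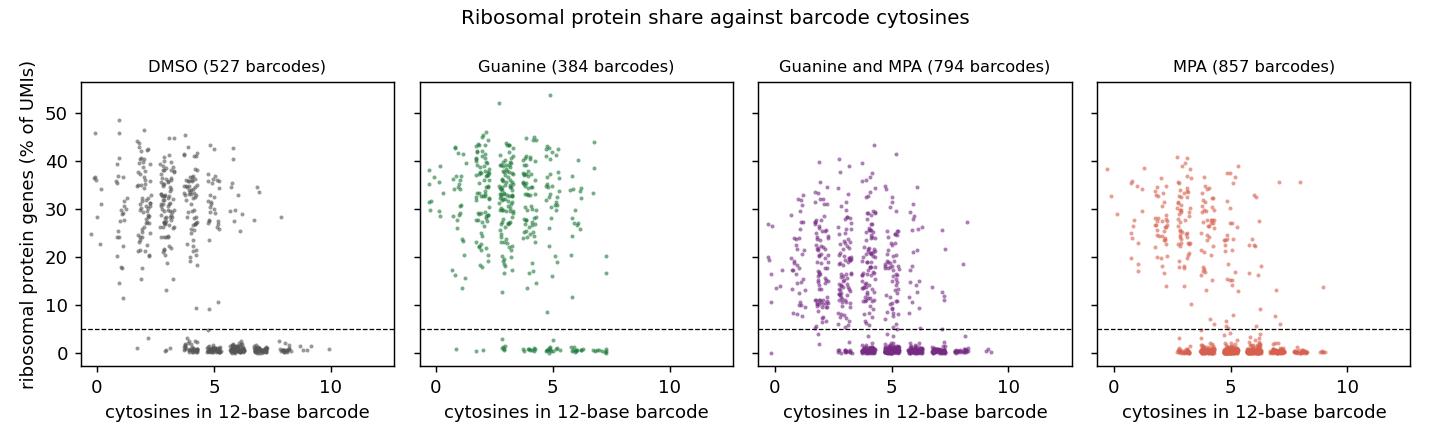
Share of UMIs from cytosolic ribosomal protein genes against the number of cytosines among the 12 bases of each barcode, one panel per treatment library. Of barcodes with at most 2 cytosines, 98.0% with DMSO, 97.4% with guanine, 97.7% with guanine and MPA and all 54 with MPA were rich.

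IMD2, the inducible gene for IMP dehydrogenase, the target of MPA (chromosome VIII, 554396 to 555967, R64), was high in 1 library, the one labelled guanine and MPA. In rich barcodes its level was 275 CPM there (Poisson interval 233 to 323, 151 UMIs), against 18.9 CPM with DMSO (9.06 to 34.8, 10 UMIs), 25.1 CPM with guanine (12.1 to 46.2, 10 UMIs) and 14.4 CPM with MPA (3.93 to 37.0, 4 UMIs). In rich barcodes of the library labelled MPA no increase of this gene, which inhibition of the enzyme is known to induce, was detectable, and the label is used below as given. IMD3, a second gene for the enzyme, was at 113 CPM with DMSO, 82.96 with guanine, 244 with guanine and MPA and 126 with MPA. IMD4 was at 217, 163, 385 and 310 CPM in that order. IMD1 had between 1 and 13 UMIs per library. These genes are near-identical over long stretches, so the division of UMIs among them is uncertain. Summed over all barcodes, IMD2 was at 20.8 CPM with DMSO, 33.3 with guanine, 163 with guanine and MPA and 38.3 with MPA, where 48 of its 52 UMIs came from poor barcodes and the ratio to DMSO was 1.84 (1.06 to 3.35).

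**Figure D2:**
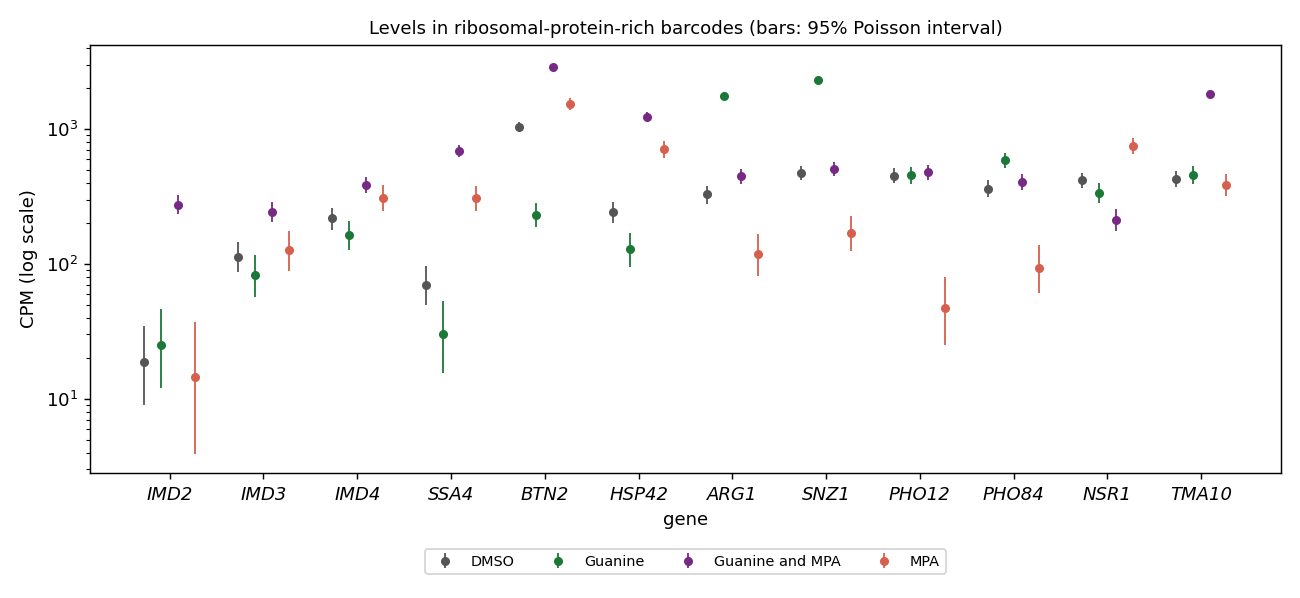
CPM on a log scale, with Poisson 95% intervals for counting error, of 12 genes in rich barcodes of the 4 treatment libraries. IMD2 stood at 275 CPM in the guanine and MPA library and below 30 CPM in the other 3.

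The comparison of the library labelled MPA with DMSO addresses the drug without added guanine. Acid phosphatase and phosphate uptake genes were lower in the library labelled MPA. PHO5, a secreted acid phosphatase, had 2 UMIs in rich barcodes against 67 with DMSO and was 17.5-fold lower (95% interval 4.67 to 148). Over all barcodes its direction was the opposite, with a log2 ratio of 2.35 (2.04 to 2.68), since 736 of its 738 UMIs in the MPA library came from poor barcodes. Its close copies PHO12 (chromosome VIII, 552099 to 553502) and PHO11 were 9.63-fold (5.52 to 18.3) and 5.76-fold lower (3.50 to 10.1). PHO84, the high-affinity phosphate transporter, was 3.85-fold lower (2.55 to 6.04). Genes of ribosome assembly were higher, among them GAR1, a component of H/ACA ribonucleoproteins, by 2.26-fold (1.94 to 2.63), NUG1, a GTPase of large-subunit export, by 2.05-fold (1.67 to 2.51), NSR1, a nucleolar RNA-binding protein, by 1.81-fold (1.49 to 2.19), and CBF5, a pseudouridine synthase, by 1.61-fold (1.42 to 1.82), whereas over all barcodes the log2 ratios of GAR1, NUG1, NSR1 and CBF5 were -0.28, -0.086, -0.49 and -0.55.

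Of the phosphate starvation list, 11 of 11 measured members were lower with MPA than with DMSO in rich barcodes, with a median log2 ratio of -1.02, below every one of the 10000 matched random lists. Ribosome biogenesis genes were higher for 24 of 32 members (median 0.23, percentile 96.6) and for 17 of 17 in low-cytosine barcodes (median 0.74), but over all barcodes 27 of 35 were lower (median -0.44). The 20 genes highest in poor barcodes held 3.47% of rich-barcode UMIs with MPA and 1.56% with DMSO, and 0.652% and 1.32% in low-cytosine barcodes. Ribosomal protein genes were lower for 120 of 136 members (median -0.40), led by RPL41B at 3.47-fold (3.07 to 3.93) and RPL41A at 2.53-fold lower (2.38 to 2.68), 2 near-identical copies, and by RPS19A at 2.27-fold lower (1.88 to 2.76). Their median was -0.20 in low-cytosine barcodes and -1.84 over all barcodes. YBR191W-A, which lies by RPL21A, and YFR032C-B, which lies by RPL29, were 4.06-fold and 2.93-fold lower, and their counts are uncertain for that reason. Glycolytic genes were lower for 13 of 16 members (median -0.46, percentile 1.04), as in PGI1, phosphoglucose isomerase, at 2.57-fold (1.86 to 3.63) and TPI1, triose phosphate isomerase, at 1.95-fold lower (1.76 to 2.17). Ergosterol synthesis genes were lower for 14 of 20 (median -0.43, percentile 0.16), with ERG4, which acts in the last step of the pathway, at 3.44-fold (2.21 to 5.59) and ERG3, a sterol desaturase, at 2.21-fold lower (1.43 to 3.54). De novo purine synthesis genes were lower for 5 of 7 (median -0.31, percentile 5.64), with ADE2 at 1.78-fold lower (0.985 to 3.41), an interval that includes 1, but over all barcodes 9 of 10 were higher (median 0.43). Further genes lower by the rule were CHK1, a checkpoint kinase, at 7.20-fold, YJR085C at 4.05-fold, SNZ1, of vitamin B6 synthesis, at 2.78-fold and HOR7, a stress-induced gene, at 2.66-fold.

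Among the genes ranked highest with MPA were SSA4, the stress-inducible Hsp70 (chromosome V, 364589 to 366517), at 4.39-fold higher (2.95 to 6.64). SSA4 resembles other Hsp70 genes, and its count is uncertain to that extent. MOT1, a remover of TATA-binding protein, at 4.84-fold (3.13 to 7.65) and AIP1, a cofactor of actin disassembly, at 4.19-fold higher (2.70 to 6.63) were at 1590 and 2130 CPM in poor barcodes of the MPA library. Its admixture, put at 18.7%, would give 298 and 399 CPM, more than the 274 and 245 CPM in rich barcodes. The estimate is thus too high for these genes. Their part from poor barcodes is not known, and a response of these genes was not shown. Of the other genes ranked highest, NAS2, TIM11, SIL1 and YHK8 had log2 ratios of -0.36, -0.22, 0.06 and 0.16 in low-cytosine barcodes against fold ratios of 23.5, 7.43, 7.87 and 5.30 in rich barcodes. A single barcode held 61.7% of NAS2, 50.1% of TIM11, 64% of YHL019W-A, 67.9% of YJL181W and 64.4% of YAR028W UMIs in rich barcodes of the MPA library. YGR022C was 13.9-fold higher (8.55 to 23.7) and SSQ1, a mitochondrial Hsp70, 15.0-fold higher (8.17 to 30.0), with 15.2% and 18.1% of their rich-barcode UMIs in one barcode. By the same estimate admixture would give 810 and 522 CPM of these genes, more than the 498 and 339 CPM in rich barcodes, so it is too high for them too. YGR022C is among the 20 genes highest in poor barcodes. The part of YGR022C and SSQ1 from poor barcodes is not known, and a response of these genes was not shown. The GMP synthesis list, made of the IMD genes and GUA1, GMP synthase, had a summed log2 ratio of 0.10 over all barcodes (-0.08 to 0.28) and 0.23 in rich barcodes (-0.05 to 0.51). Its median over all barcodes lay at percentile 30.9. Its direction over all barcodes depended on the processing, with 0.57 after thinning (0.22 to 0.94) and -0.20 with median of ratios (-0.38 to -0.012).

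Guanine against DMSO addresses guanine without the drug. Amino acid synthesis genes, targets of the transcription factor Gcn4, were higher with guanine. ARG1, argininosuccinate synthetase (chromosome XV, 219211 to 220473), was 5.37-fold higher in rich barcodes (4.54 to 6.39), ARG8, of ornithine synthesis, 6.50-fold (3.89 to 11.5), HIS4, of histidine synthesis, 4.45-fold (3.07 to 6.57) and HIS3, of the same pathway, 4.25-fold (3.4 to 5.35). The vitamin B6 synthesis pair SNZ1 and SNO1, which lie side by side on chromosome XIII, were 4.92-fold (4.27 to 5.68) and 7.54-fold higher (4.86 to 12.2). Chaperone genes were lower, as in HSP82, a cytosolic Hsp90 with the close copy HSC82, at 2.40-fold (2.03 to 2.84), and BTN2, a protein-sorting factor (chromosome VII, 772454 to 773686), at 4.45-fold lower (3.56 to 5.61).

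By list, 28 of 30 Gcn4 targets were higher with guanine than with DMSO (median log2 ratio 1.21, above every random list). Methionine and sulfur genes were higher for 10 of 11 (median 0.53, percentile 99.3), with MET16, of sulfate reduction, at 3.55-fold (2.69 to 4.72) and MET14, adenylylsulfate kinase, at 2.22-fold (1.75 to 2.82). Iron starvation genes were higher for 7 of 9 (median 0.74, percentile 99.8), including FIT3, a cell wall protein of siderophore retention, at 3.63-fold (2.29 to 5.93) and FET3, the iron oxidase, at 2.12-fold (1.68 to 2.68). De novo purine synthesis genes were higher for 7 of 9 (median 0.63, percentile 98.9), with ADE12, adenylosuccinate synthase, at 2.60-fold (1.82 to 3.77) and ADE1 at 2.39-fold (1.60 to 3.62). Nuclear genes of the respiratory chain and ATP synthase were higher for 17 of 23 (median 0.21, percentile 95.2), as in COX9 at 1.98-fold (1.61 to 2.44). Drug efflux genes were higher for 5 of 8 (median 0.60, percentile 99.4), led by the transporter FLR1 at 2.83-fold (2.32 to 3.47), although over all barcodes their median was -0.18 and their summed log2 ratio 0.26 (0.14 to 0.39). Ribosomal protein genes were higher for 84 of 137 (median 0.13, percentile 99.9; low-cytosine median 0.06), with RPL39 lower by 3.33-fold (2.61 to 4.29).

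Ribosome biogenesis genes were lower with guanine for 27 of 30 members (median -0.62, below every random list), as in SPB1, an rRNA methyltransferase, at 2.69-fold (2.01 to 3.65). Hsf1-target chaperones were lower for 14 of 14 (median -0.45, percentile 2.80) and proteasome genes for 27 of 32 (median -0.38, percentile 3.26), the latter led by RPN1 at 2.74-fold (2.08 to 3.66) and RPN2 at 2.57-fold (2.07 to 3.23). Glycolytic genes were lower for 12 of 17 (median -0.39, percentile 0.49), with GPM1, phosphoglycerate mutase, at 2.08-fold (1.93 to 2.24) and TDH3, which has the close copy TDH2, at 1.74-fold (1.68 to 1.81), while over all barcodes their median was 0.09 and their summed log2 ratio -0.10 (-0.13 to -0.074). Cell wall genes were lower for 9 of 12 (median -0.60, percentile 0.25), including CWP2 at 2.32-fold (1.85 to 2.92). The rule also named AAD4 (9.44-fold), NIT1 (7.69-fold), FRM2 (7.55-fold), TMT1 (6.43-fold), YIL165C (6.18-fold), SPG4 (5.85-fold) and YLR346C (5.43-fold) as higher. It named YPL250W-A (5.76-fold), BDP1 (4.96-fold), RAD27 (4.13-fold), CDC5 (4.08-fold), NOP8 (3.92-fold), DSE3 (3.87-fold), CUR1 (3.51-fold), ERG6 (3.46-fold), HRP1 (3.35-fold) and FPR4 (2.88-fold) as lower. The summed log2 ratio of the GMP synthesis list was 0.10 over all barcodes (-0.16 to 0.35, percentile 65.85) and -0.31 in rich barcodes (-0.59 to -0.03).

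Guanine and MPA against DMSO sets both compounds against the control. IMD2 was 14.6-fold higher in rich barcodes (7.71 to 31.0), IMD3 2.15-fold (1.58 to 2.97) and IMD4 1.77-fold higher (1.40 to 2.24), whereas GUA1 was 1.76-fold lower (1.28 to 2.44). FRM2 and HBN1, neighbouring genes of nitroreductase-like proteins on chromosome III, were 11.2-fold (7.78 to 16.8) and 7.66-fold higher (5.92 to 10.1). SSA4 was 9.78-fold higher (6.96 to 14.1). Ribosomal protein genes were lower for 136 of 137 members (median log2 ratio -0.78, below every random list), led by RPL6B at 2.69-fold (2.24 to 3.24), RPL12A at 2.66-fold (2.35 to 3.02) and RPS19A at 2.59-fold lower (2.22 to 3.03), each with a near-identical or similar partner gene. The median was -0.79 in low-cytosine barcodes and -1.04 over all barcodes. Low-cytosine barcodes were chosen by their bases, but 98.0% with DMSO and 97.7% with guanine and MPA were also rich. The filter of lists also required the same side there.

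Growth-related lists were lower along with them. Ribosome biogenesis genes were lower for 30 of 33 (median -0.47, below every random list), with NOG2 at 2.63-fold (1.68 to 4.23) and NSR1 at 1.97-fold (1.56 to 2.48). RNA polymerase I and III subunits were lower for 13 of 15 (median -0.25, percentile 0.020), as in RPA34 at 1.43-fold (1.16 to 1.77), although the members summed over all barcodes had a log2 ratio of 0.023 (-0.067 to 0.11). Translation factors were lower for 22 of 24 (median -0.33, percentile 0.78), as in SUI1, initiation factor eIF1, at 2.19-fold (1.74 to 2.76). Pyrimidine synthesis genes were lower for 8 of 9 (median -0.62, below every random list), with URA1, dihydroorotate dehydrogenase, at 1.83-fold (1.58 to 2.13) and URA7, CTP synthase, at 1.83-fold (1.28 to 2.63).

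Stress and sulfur genes were higher with guanine and MPA than with DMSO. Of the induced environmental stress genes 16 of 17 were higher (median 0.997, above every random list), among them the small heat shock protein HSP42 at 5.09-fold (4.21 to 6.20) and TMA10 at 4.28-fold (3.70 to 4.97). Hsf1-target chaperones were higher for 14 of 14 (median 0.70, percentile 99.98), led by HSP82 at 2.80-fold (2.55 to 3.08). Methionine and sulfur genes were higher for 13 of 13 (median 1.36, above every random list), with MET3, ATP sulfurylase, at 10.3-fold (4.48 to 29.1) and MET10, of sulfite reductase, at 4.47-fold (3.27 to 6.22). Iron starvation genes were higher for 10 of 10 (median 0.93, percentile 99.9), with FIT3 at 5.05-fold (3.3 to 8.0), and drug efflux genes for 8 of 8 (median 1.18, percentile 99.99), with the polyamine transporter TPO1 at 2.84-fold (2.07 to 3.94). De novo purine synthesis genes were higher for 7 of 9, with a median of 0.25 at percentile 36.8. The median ratio of all genes in this comparison was 0.27, against 0.21 for guanine and MPA against MPA and 0.28 against guanine, and the list percentiles are relative to genes of like expression. AFI1 was ranked first at 24.7-fold (10.3 to 77.4) and is among the 20 genes highest in poor barcodes. It took 1.30% of poor-barcode UMIs with guanine and MPA and 0.032% with DMSO. Its part from poor barcodes in rich barcodes is not known, and a response of AFI1 was not shown. Over all barcodes the GMP synthesis list had a summed log2 ratio of 0.68 (0.50 to 0.86) and its median lay at percentile 92.3. In rich barcodes these values were 0.88 (0.68 to 1.09) and 99.2 without IMD1, which had too few UMIs there, and the sum was 0.91 with it.

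Guanine and MPA against the library labelled MPA addresses guanine in the presence of the drug. IMD2 was 19.1-fold higher with guanine and MPA (7.29 to 70.9) and IMD3 1.93-fold higher (1.32 to 2.89). IMD4 differed less, at 385 CPM against 310 CPM with MPA, and GUA1 went the other way, at 115 CPM against 188 CPM. The phosphate genes PHO5, PHO12, PHO11 and PHO84 were 30.6-fold (8.28 to 255), 10.2-fold (5.85 to 19.4), 6.09-fold (3.71 to 10.7) and 4.33-fold higher (2.88 to 6.78). HSP12, a membrane-binding stress protein, was 9.48-fold (5.44 to 18.1) and TMA10 4.71-fold higher (3.86 to 5.81). NUG1, NSR1 and GAR1 were 3.56-fold (2.81 to 4.52), 3.55-fold (2.82 to 4.50) and 2.99-fold lower (2.54 to 3.52).

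Phosphate starvation genes were higher for 11 of 11 members with guanine and MPA than with MPA (median log2 ratio 1.34, percentile 99.99). Methionine and sulfur genes were higher for 13 of 13 (median 1.02, percentile 99.9), as in MET14 at 3.16-fold (2.33 to 4.37). Chaperones were higher for 13 of 14 (median 0.45, percentile 98.9), as in HSP10, a mitochondrial chaperonin, at 2.15-fold (1.81 to 2.56). Iron starvation genes were higher for 9 of 10 (median 1.03, percentile 99.95; over all barcodes -0.13, with a sum of 0.39), including FIT2 at 4.37-fold (3.23 to 6.02). Stress genes were higher for 12 of 15 (median 1.07, above every random list; over all barcodes -0.0072, with a sum of 0.57), including HOR7 at 3.16-fold (2.78 to 3.60). De novo purine synthesis genes were higher for 7 of 8 (median 0.79, percentile 97.48; over all barcodes -0.27), with ADE12 at 2.38-fold (1.42 to 4.22) and ADE13 at 2.53-fold (1.22 to 5.88). Ribosome biogenesis genes were lower for 31 of 32 (median -0.71, below every random list), while their median over all barcodes was -0.015. Ribosomal protein genes were lower for 117 of 136 in rich barcodes (median -0.39) and for 121 of 132 in low-cytosine barcodes (median -0.59), yet higher for 131 of 137 over all barcodes (median 0.79). RPL31B and RPL8A were 2.59-fold (2.29 to 2.95) and 2.71-fold lower (2.16 to 3.41) in rich barcodes.

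The rule further named RGI2 (18.2-fold), YFR052C-A (12.4-fold), RTC3 (9.09-fold), YCT1, a cysteine transporter (5.26-fold), FIT3 (4.91-fold) and ALD4, mitochondrial aldehyde dehydrogenase (4.26-fold), as higher with guanine and MPA than with MPA. It named YHL019W-A (24.8-fold), SSQ1 (4.23-fold), YGR022C (3.74-fold), YHK8 (3.24-fold), NOP13 (2.68-fold), DBP3 (2.54-fold) and HYP2, translation factor eIF5A (2.17-fold), as lower. In low-cytosine barcodes YHK8 had a log2 ratio of 0.21 (-1.31 to 2.01), too few UMIs to give a direction. For YHL019W-A, SSQ1, YGR022C and YHK8, admixture of poor barcodes was put at 18.7% with MPA against 9.29% with guanine and MPA. It would give 306, 522, 810 and 587 CPM in the MPA library, more than the 180, 339, 498 and 491 CPM in its rich barcodes. The estimate is thus too high for these genes, and their part from poor barcodes is not known. Over all barcodes FIT3 had a log2 ratio of -0.0012 (-0.28 to 0.27), no difference, and HYP2 one of 0.16 (0.062 to 0.26), opposite to its direction in rich barcodes. PHO5 had a log2 ratio of -2.09 over all barcodes, where all but 2 of its UMIs in the MPA library came from poor barcodes. The GMP synthesis list had a summed log2 ratio of 0.58 over all barcodes (0.43 to 0.73, percentile 88.3) and 0.67 in rich barcodes (0.43 to 0.93, percentile 90.1). Over all barcodes it was 0.032 after thinning (-0.26 to 0.32) and -0.042 as the mean of barcode CPM.

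Guanine and MPA against guanine addresses the drug when guanine was present. With the drug SSA4 was 22.7-fold (12.8 to 44.3), BTN2 12.4-fold (10.1 to 15.5), HSP42 9.61-fold (7.23 to 13) and HSP82 6.71-fold higher (5.76 to 7.86). IMD3 was 2.94-fold (2.00 to 4.45) and IMD4 2.35-fold higher (1.77 to 3.16), and IMD2 10.95-fold higher (5.79 to 23.3). GUA1 went the other way, at 115 CPM with guanine and MPA against 184 CPM with guanine. ARG3, ornithine carbamoyltransferase, was 6.98-fold (4.11 to 12.5), ARG1 3.95-fold (3.41 to 4.59) and SNZ1 4.62-fold lower (4.03 to 5.30). YLR366W was 9.82-fold lower (5.80 to 17.8). ARG8 was 2.58-fold lower (1.79 to 3.76), and 1 barcode held 61.7% of its UMIs in rich barcodes of the guanine and MPA library, without which the log2 ratio was -2.63.

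Stress genes were higher for 15 of 16 members with guanine and MPA than with guanine (median log2 ratio 1.57), chaperones for 14 of 14 (median 1.30) and proteasome genes for 32 of 32 (median 0.78, percentile 99.6), the last led by RPN2 at 4.49-fold (3.65 to 5.56). With proteasome genes summed over all barcodes and scaled by median of ratios, the log2 ratio was -0.00017. Gcn4 targets were lower for 28 of 30 (median -1.10, below every random list), as in ILV3, of branched-chain amino acid synthesis, at 5.37-fold (3.52 to 8.45). Ribosomal protein genes were lower for 132 of 137 (median -0.86, and the same to 2 decimals in low-cytosine barcodes), as in RPL15A at 3.18-fold (2.94 to 3.45). Translation factors were lower for 16 of 24 (median -0.28, percentile 4.35), with SUI1 at 2.63-fold (2.08 to 3.34), and HYP2 was the exception named by the rule, at 2.11-fold higher (1.90 to 2.34). Of 7 TCA cycle genes 5 were lower (median -0.37, percentile 2.45), as in IDH1, isocitrate dehydrogenase, at 2.24-fold (1.63 to 3.11). De novo purine synthesis genes were lower for 6 of 9 (median -0.28, percentile 1.86), with ADE4 at 1.98-fold (1.21 to 3.26), while over all barcodes their median was 0.0067 and their summed log2 ratio -0.088 (-0.23 to 0.059). The summed log2 ratio of the GMP synthesis list was 0.57 over all barcodes (0.35 to 0.80, percentile 70.0) and 1.16 in rich barcodes (0.92 to 1.41, percentile 99.8). Over all barcodes it was 0.18 with median of ratios (-0.04 to 0.41) and 0.24 after thinning (-0.16 to 0.65), intervals that include 0.

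**Figure D3:**
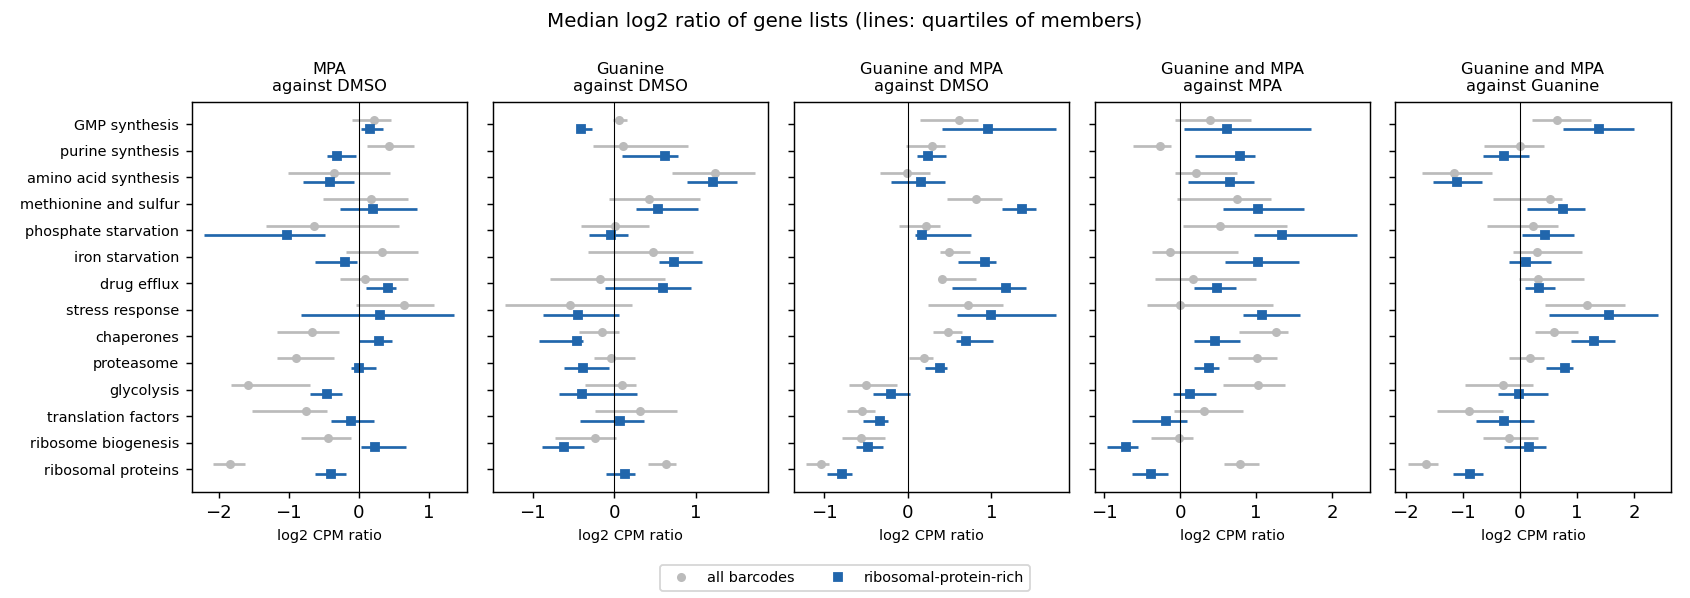
Median log2 CPM ratio of 14 gene lists in the 5 comparisons, over all barcodes and in rich barcodes, with lines for the quartiles of the members. In guanine and MPA against MPA, ribosomal protein genes had a median of 0.79 over all barcodes and -0.39 in rich barcodes.

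The ratios summed over all barcodes were led by genes whose UMIs came largely from a single barcode. In MPA against DMSO, snR73, a small nucleolar RNA, was 159-fold (68.1 to 492) and YHL019W-A 60.9-fold higher (38.9 to 101), with 80.2% and 70.4% of their MPA UMIs in 1 barcode. PHD1 and YJR085C were 15.6-fold and 15.3-fold lower, with 92.4% and 57.2% of their DMSO UMIs in 1 barcode. In guanine against DMSO, YIL060W (13-fold) and SNA4 (11.9-fold) were highest and TRM11 (56.0-fold) and DYN1 (28.7-fold) lowest, with 97.0%, 82.3%, 91.8% and 50.6% in 1 barcode of the library with the higher level. In guanine and MPA against DMSO, YER010C (76.1-fold) and AFI1 (50.9-fold) were highest and CRR1 (14.3-fold) and DIE2 (13.9-fold) lowest, with 94.2%, 64.9%, 94.3% and 83% in 1 barcode. In guanine and MPA against MPA these were ERG28 (107-fold), YOR146W (78.2-fold), OPI11 (40.1-fold) and RAD53 (24.8-fold), with 89.4%, 99.0%, 86.9% and 81.9%. AFI1 (151-fold) and YER010C (82.5-fold) led guanine and MPA against guanine, in which TAR1 (13.2-fold, 90.7% in 1 barcode of the guanine library) and YLR366W (12.9-fold, 4.35%) were lowest.

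Whether genes that differed with the drug alone also differed with the drug when guanine was present was described by correlating the ratio MPA over DMSO with the ratio guanine and MPA over guanine, which share no library. Over all barcodes Pearson's r across 5190 genes was 0.50 and Spearman's rho 0.51. Poor barcodes held 79.6% of UMIs with MPA and 38.9% with DMSO, and 50.7% with guanine and MPA and 11.7% with guanine. Both ratios thus set a library with a larger poor share over one with a smaller share. The correlation over all barcodes therefore cannot tell the drug from this difference in barcodes. In rich barcodes r was 0.24 and rho 0.26 across 2564 genes, and in low-cytosine barcodes r was 0.31 and rho 0.35 across 743 genes. The ratio guanine over DMSO and the ratio guanine and MPA over MPA had r of 0.18 and rho of 0.16 across 2673 genes in rich barcodes. Among ratios that share the DMSO library, MPA over DMSO and guanine and MPA over DMSO had r of 0.36 in rich barcodes, where simulations without effects gave 0.42. The covariance was 0.151 and the simulated covariance 0.0321. For guanine over DMSO and guanine and MPA over DMSO, r was 0.28 against 0.48 in simulations, with covariances of 0.111 and 0.0361. For MPA over DMSO and guanine over DMSO, r was 0.051 against 0.39, with covariances of 0.0219 and 0.0321. The simulations held Poisson error only. An r below or a covariance above the simulated value therefore cannot tell a treatment effect from other differences between libraries, those of the shared DMSO library included.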

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

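The tests of poor barcodes, of list directions under a label swap, of reads shared with IMD3, of reads from poor barcodes and of admixture were chosen after the result was seen, and so were the rich and low-cytosine barcodes used for the list differences below. The label swap correlation, UMI depth and within-cell stress tests were written before their values were seen.

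Scaled by total UMIs, several lists went opposite ways with the drug depending on the presence of guanine, in rich barcodes, where DMSO was the reference without guanine and the guanine library the reference with it. Phosphate starvation genes had a summed log2 ratio of -1.07 (-1.20 to -0.93) without guanine and 0.33 (0.25 to 0.42) with it, a difference of 1.40. Ergosterol synthesis genes had -0.32 (-0.43 to -0.21) and 0.59 (0.49 to 0.70), a difference of 0.91. Glycolytic genes had -0.25 (-0.28 to -0.22) and 0.41 (0.38 to 0.44), a difference of 0.66. Translation factors had 0.094 (0.055 to 0.13) and -0.34 (-0.38 to -0.31), a difference of -0.44. The median gene of guanine and MPA against guanine was itself at 0.28, so that with median of ratios the values with guanine were 0.050 (-0.037 to 0.14) for phosphate starvation, no longer an opposite direction, 0.31 (0.21 to 0.41) for ergosterol synthesis, 0.13 (0.10 to 0.16) for glycolysis and -0.63 (-0.66 to -0.59) for translation factors. With totals without ribosomal protein genes, values of MPA against DMSO in rich barcodes fell by 0.136. The translation factor value without guanine, 0.094 (0.055 to 0.13), then lay below 0, so these genes were lower in both settings. In low-cytosine barcodes this fall was 0.076, and their value without guanine, 0.31 (0.23 to 0.38), stayed above 0. With 1 library per treatment these differences were not tested. With total UMIs their directions were the same in low-cytosine barcodes by construction. Only lists with opposite directions in both rich and low-cytosine barcodes were kept here, so this is no separate check. Over all barcodes phosphate starvation, glycolysis and translation factor genes were lower in both settings.

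In the mixed-species library, which no comparison used, 127 UMIs of 107 listed genes were found in 95 of 200 barcodes, with at most 5 UMIs in a barcode. None of the 5942 gene identifiers of the deposited S. bayanus annotation was in its table (0 identifiers).

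Poor barcodes were present in all 4 treatment libraries, and their levels followed gene length. Cells with less ribosomal protein mRNA would carry the same bead barcodes as other cells, yet cytosine was higher in poor than in rich barcodes by 15.5 to 23.0 percentage points over the 4 libraries, which argues against such cells as the whole source. Sequences that are not bead barcodes remain a candidate source, since a gap above 5 points was set for them and the smallest gap was 15.5 points. Levels in poor barcodes had a rank correlation with coding length across genes that was higher by 0.590 to 0.667 than in rich barcodes, consistent with reads that start along the whole gene, from DNA or from priming within transcripts. The data do not separate those 2 origins.

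IMD2 was high in the library labelled guanine and MPA, though guanine feeds the pathway that the enzyme serves, and not in the library labelled MPA. Reads shared with IMD3 would keep the ratio of IMD2 to IMD3 constant, but that ratio was 6.76-fold higher than with DMSO (3.33 to 13.7), and reads from poor barcodes do not account for the level, since poor barcodes had 0.193 times the IMD2 CPM of rich ones (0.126 to 0.287). A swap of the 2 labels would turn the effect of guanine around. Over all barcodes guanine and MPA over MPA correlated with guanine over DMSO across genes at r of 0.33. This value cannot bear on a swap, since the poor share of UMIs was lower in the first library of both ratios. It was 50.7% against 79.6% and 11.7% against 38.9%. In rich barcodes r was 0.185 and in low-cytosine barcodes 0.182, above the bound of 0.1 set against a swap. Without ribosomal protein genes and genes higher in poor barcodes these were 0.28 and 0.26. That bound assumed that guanine acts in the same direction with and without the drug, but of 9 lists beyond percentile 5 or 95 in both rich-barcode comparisons 6 kept their direction and 3 turned, among them ribosomal protein genes (0.13 and -0.39) and chaperones (-0.45 and 0.45), so a swap stays open. A library labelled MPA that had not met an effective dose, and a biological difference between the treatments, may each account for the pattern and were not tested.

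Ribosomal protein genes were lower with guanine and MPA than with DMSO in rich barcodes. Admixture of the poor-barcode profile was 3.16 percentage points higher in that library by the 20 genes highest in poor barcodes, well below the 20 points or more that such an admixture would need. Thinned to 500 UMIs per barcode, the log2 ratio of the ribosomal protein share was -0.756 (-0.777 to -0.735). Thinning gives barcodes equal weight but keeps the expected share of each, so it shows only that the weight of deep barcodes is not the source. It cannot tell whether depth went with the shares themselves. If a stress response in part of the cells lowered these transcripts, barcodes with more stress transcripts could have fewer of them, but the rank correlation was -0.0756 (-0.180 to 0.0307), and its interval reaches beyond the bound of -0.1 set for deciding. A response shared by all cells of that library, or a difference between cultures, was not tested.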

How the results depend on the processing

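The choices of rich barcodes, of low-cytosine barcodes, of barcodes by glycolysis and translation share and the removal of each gene's leading barcode were made after the data were seen, and the other alternatives were planned. All values are log2 ratios unless stated. Across 1704 alternative values of single genes and lists, 950 stayed within the counting interval, 701 moved beyond it and 53 changed direction, 30 of them with an interval that includes 0, so that no opposite direction is shown there. A change of direction was counted only where the interval of the value first reported excluded 0. Other changes of sign are counted as moved or as within the interval. Of values of the rich barcodes, 10 of 142 changed direction and 92 moved over all barcodes, and 3 of 132 changed direction and 54 moved in low-cytosine barcodes. None changed direction with median of ratios (41 of 142 moved), by glycolysis and translation share (12 of 142), without the leading barcode (8 of 142), with totals without ribosomal protein genes (34 of 137) or after thinning (36 of 136). Part of this was fixed by the choices. Genes were ranked without their leading barcode, and most lists were kept by their side in low-cytosine barcodes. The glycolysis and translation choice left out only 0, 5, 17 and 8 rich barcodes with DMSO, guanine, guanine and MPA, and MPA. No paired analysis was possible because each treatment had 1 library, and leaving out replicates does not apply. The planned species calls were not run, since no S. bayanus gene was listed. Depth limits the smallest groups most: 54 low-cytosine barcodes of the MPA library held 59161 UMIs, where 0 UMIs allow up to 50.7 CPM, as for IMD2. Where no construction is named below, the cause was not tested.

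The GMP synthesis list summed over all barcodes was 0.10 in MPA against DMSO. It was -0.20 with median of ratios, -0.13 with totals without ribosomal protein genes, -0.21 in barcodes at or above the median, 0.48 as the mean of barcode CPM, 0.57 after thinning, 0.31 in low-cytosine barcodes and -0.10 without the leading barcode. In guanine against DMSO it was -0.31 in rich barcodes, -0.30 by glycolysis and translation share and -0.50 in low-cytosine barcodes, against 0.10 (0.095) over all barcodes. In guanine and MPA against DMSO it stayed positive, at 0.39 with a minimum of 200 UMIs, which leaves out IMD2, 0.44 as the mean of barcode CPM, 0.91 in rich barcodes with IMD1 and 0.92 by glycolysis and translation share. For guanine and MPA against MPA it was 0.996 in barcodes at or above the median, 0.032 after thinning, 0.76 without the leading barcode and, with the sign reversed, -0.042 as the mean of barcode CPM. It also stayed positive in guanine and MPA against guanine, at 0.18 with median of ratios, 0.23 without ribosomal protein genes in the total, 0.30 with the minimum of 200 UMIs, 0.24 after thinning, 1.16 in rich barcodes, 1.16 by glycolysis and translation share and 1.26 in low-cytosine barcodes.

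The correlation of the drug's ratios without and with guanine was 0.66 with a minimum of 200 UMIs, 0.54 after thinning, 0.24 in rich barcodes and 0.31 in low-cytosine barcodes, against 0.50 over all barcodes. The values of 0.66, 0.54 and 0.50 include poor barcodes, whose share of UMIs was larger in both libraries with the drug. Median UMIs per barcode without ribosomal protein genes were 912 with DMSO, 626 with guanine, 816.5 with guanine and MPA and 855 with MPA, fewer by construction. Mean UMIs were 1644, 1173, 1402 and 1586. Rich barcodes had medians of 1484.5 with DMSO and 1065.5 with guanine and MPA.

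Lists that changed direction between all barcodes and the other barcode choices did so mostly in comparisons with MPA. De novo purine synthesis in MPA against DMSO was -0.25 in rich barcodes, -0.21 by glycolysis and translation share and -0.48 in low-cytosine barcodes. Ribosome biogenesis was 0.37, 0.41 and 0.74 in that order, and -0.58 for the rich-barcode members over all barcodes. Purine synthesis in guanine and MPA against MPA was 0.53, 0.52 and 0.74, and -0.92 for the rich-barcode members over all barcodes. For ribosomal protein genes the values were -0.38, -0.46 and -0.57, and 0.83 over all barcodes, and ribosome biogenesis genes were 0.020 over all barcodes. RNA polymerase I and III genes in guanine and MPA against DMSO were 0.023 over all barcodes. In guanine against DMSO over all barcodes, proteasome genes were -0.083 with total UMIs and became positive, at 0.090 with median of ratios, 0.10 without ribosomal protein genes in the total, 0.014 as the mean of barcode CPM and 0.0097 after thinning. Glycolytic genes, at -0.10 with total UMIs, did so too, at 0.072, 0.083, 0.061 and 0.032. Proteasome genes in guanine and MPA against guanine were -0.00017 with median of ratios.

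Of genes named in rich barcodes, PHO5 was 2.35 over all barcodes in MPA against DMSO and -2.09 in guanine and MPA against MPA, where FIT3 was -0.0012 (-0.28 to 0.27) and HYP2 0.16. In low-cytosine barcodes NAS2 was -0.36 and TIM11 -0.22 in MPA against DMSO, and YHK8 was 0.21 in guanine and MPA against MPA, all with intervals that include 0. Genes named over all barcodes took the other sign in some barcode choices or without single barcodes, with intervals that include 0 for all the values below except that of DYN1 (0.49 to 2.07). PHD1 in MPA against DMSO was 0.016 in rich barcodes, 0.0087 by glycolysis and translation share and 0.25 in low-cytosine barcodes. YIL060W in guanine against DMSO was -1.57 without the 5% of barcodes with most UMIs, -0.17 in rich barcodes, -0.16 by glycolysis and translation share and -1.06 without its leading barcode, and DYN1 was 1.27 in low-cytosine barcodes. For guanine and MPA against DMSO, CRR1 was 0.11 without the 5% of barcodes with most UMIs and 0.20 without its leading barcode, and DIE2 was 0.023 without that 5%, 0.48 in rich barcodes, 0.76 by glycolysis and translation share and 1.49 in low-cytosine barcodes. YOR146W in guanine and MPA against MPA was -0.30 without the 5% of barcodes with most UMIs, -0.47 in low-cytosine barcodes and -0.075 without its leading barcode. TAR1 in guanine and MPA against guanine was 0.21 in rich barcodes and 0.18 by glycolysis and translation share.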

Other observations

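These values were chosen for description after the data were seen. Shares of some genes highest in poor barcodes varied among the libraries, in part through single barcodes. AFI1 took 1.30% of poor-barcode UMIs with guanine and MPA, against 0.032% with DMSO, 0.015% with guanine and 0.062% with MPA. FCY22, a purine-cytosine permease homologue, took 1.24% with guanine and 0.147% with DMSO, and DYN1, the dynein heavy chain, 1.62% with DMSO and 0.053% with guanine. Over all barcodes, 1 barcode held 64.9% of AFI1 UMIs with guanine and MPA, 88.0% of FCY22 UMIs with guanine and 50.6% of DYN1 UMIs with DMSO. Across genes, poor-barcode levels of the MPA library and the guanine and MPA library had a rank correlation of 0.754, those of DMSO and MPA 0.695, and those of DMSO and guanine 0.237. The guanine library had 52 poor barcodes with 52546 UMIs, against 337344 UMIs with DMSO and 1082147 with MPA. Few counts lower such a correlation, so the value with guanine is not comparable with the others.

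Within rich barcodes thinned to 500 UMIs, the median share of 44 stress and Hsf1 genes among UMIs outside ribosomal protein genes was 2.02% with DMSO, 1.46% with guanine, 3.14% with guanine and MPA and 2.40% with MPA. The rank correlation of this share with the ribosomal protein share over barcodes was -0.17 with DMSO, -0.16 with guanine and 0.19 with MPA. Barcodes are not replicates, so no test between libraries was made.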
